A study of Homo sapiens with 104 samples.

How the data were processed

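RNA was measured by poly(A)-selected RNA-seq in MDA-MB-436 cells, a human triple-negative breast cancer line that expressed dCas9-KRAB, a catalytically dead Cas9 fused to a repressor domain. Cells were transfected with pools of guide RNA plasmids, and RNA was taken 48 h later. The 104 libraries fell into 34 groups. There were 30 groups with guides to a super-enhancer, a dense cluster of enhancers, with 3 libraries each (replicates 1, 3 and 4). Guides to the promoter and to an enhancer of CSF1 were the positive controls, with 4 libraries each, and 2 scrambled guide pools were the negative controls, with 3 libraries each. The fourth library of each CSF1 group is titled replicate 2, but its column name differs from those of the other 3 and gives number 3, so it may hold a second guide set at replicate 3. The title was followed, which sets n = 4 and the number used in the replicate block. The labels speak of transfection replicates and do not say whether these came from separate cultures, so each p-value measures the spread between these libraries, part of which may be technical.

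The values as deposited are estimated counts per gene symbol, which the authors computed with Salmon 1.4.0 and did not normalise to depth. The labels also name STAR 2.7.6a, Picard 2.22.4, FastQC 0.11.9 and genome build hg38. The transcript annotation and the options of these tools are not given in the sources used here. Of all values, 89.36% were whole numbers within 0.001, and all were rounded to whole counts. The table held 58387 gene symbols. Totals per library ranged from 16223730 to 28063763 counts. Coordinates, transcript length and GC content came from GENCODE 29, to which 36930 symbols could be matched.

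Counts were modelled with edgeR 4.0.16 in R 4.3.3 in 1 fit of all 104 libraries with a mean per group. Scaling factors were from TMM, and filterByExpr by group left 17701 genes. Each target was tested with the robust quasi-likelihood test against the equally weighted mean of scramble 1 and scramble 2. Each super-enhancer was also tested against the equally weighted mean of the 33 other groups, in which the scrambles are 2 of the 33. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene counted as changed at an adjusted p under 0.05. Log2 changes are from edgeR, standard errors (SE) were derived from the test statistic, and levels are TMM-scaled counts relative to library size (CPM), given as mean ± SD. All tests were two-sided. This is called the planned design.

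Named genes were chosen by a rule. CSF1 came first. For each CSF1 target and the 5 super-enhancers with the most calls against the scrambles, the rule took up to 10 lower and 10 higher genes with the smallest p past the threshold. Every library of the target had to lie on the same side of the control mean. For each other super-enhancer it took 3 lower genes and 1 higher gene against all other groups, and for a shared response the 10 genes lower and the 10 genes higher in the most super-enhancers. Up to 4 members with the smallest p were taken from each gene list.

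The 22 gene lists were basal and TNBC-associated, luminal breast, haematopoietic, fibroblast, mesenchymal, epithelial, mitosis, DNA replication, interferon response, NF-kB and cytokines, p53 targets, ATF4 stress response, ER unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta targets, YAP and TEAD targets, immediate early genes, matrix proteases and invasion, cytosolic ribosomal proteins, mitochondrial genome transcripts and replication-dependent histones. The luminal, haematopoietic and fibroblast lists stand for other cell types, and the mitochondrial and histone lists for RNA quality and poly(A) selection. Lists were tested with camera in limma 3.58.1 on signed z values, with the inter-gene correlation preset at 0.01 and again with an estimated correlation, adjusted over all lists and super-enhancers. The planned design, the lists, the rule for named genes and most alternative settings were fixed before the data were examined.

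Genes lying together that were lower in a super-enhancer were looked for in windows of 500 kb on either side of each tested gene, with at least 3 genes. The sum of their z values, scaled by the root of their number, was set against the lowest sums of 100 random sets of 3 libraries from different groups. The z values were from edgeR for the super-enhancers and from limma-trend for the random sets.

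For each library, the slope of log2 expression on log2 transcript length was computed against the mean of all libraries, over 10099 genes with a mean log2 CPM above 3. A length could be given to 86.9% of tested genes. After the slopes had been seen, 3 further designs were fitted. They added the length slope alone, the length slope with the replicate number, and both with a slope on GC content. The design with the replicate number and the length slope is called the adjusted design, and its results were chosen after the data were seen. For it the named genes were taken by the same rule. For each super-enhancer, the gene with the smallest p among those lower than in all other groups was also followed across designs and with each library of that super-enhancer left out in turn (limma-trend).

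Alternatives covered other scaling factors, no filter and a filter at 5 CPM, DESeq2 1.42.0, the replicate number as a block, each scramble alone, fits of a target and the scrambles alone, and each replicate number and scramble library left out. A replicate number was left out of every target at once and kept in the scrambles. A stricter adjusted p of 0.01, a 1.5-fold limit and an adjustment over all 32 targets together were also tried. Added after the data were seen were the 3 further designs and a fit without libraries of a length slope above 0.2. Other assignments of libraries to groups, up to 100 a result, were counted with limma-trend. The pipeline was tested on simulated data with known changes. In simulated counts for SE39 against the scrambles, edgeR called 6% of 50 genes changed by a log2 of 0.25, 38% at 0.5, 50% at 1 and 78% at 2. It also called 5 of the unchanged genes there. The simulated counts held no gradient of transcript length and no effect of the replicate number. No library was left out of the planned design.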

Results

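The data were gene counts from libraries of MDA-MB-436 cells, in which dCas9-KRAB was led to 1 of 32 sites by pools of guide RNAs. Each of 30 super-enhancers, numbered SE2 to SE87, had 3 libraries, and the promoter and an enhancer of CSF1 had 4 each. The 2 scrambled guide pools gave 6 control libraries. Totals per library ran from 16223730 to 28063763 counts, and 17701 genes were tested.

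The first question was whether guides to CSF1 lowered CSF1, the gene of the macrophage colony-stimulating factor (chromosome 1, 109910242 to 109930992, plus strand). CSF1 stood at 236.7 ± 4.42 CPM in the scrambles (SD, n = 6), 169.0 ± 3.19 CPM with promoter guides (n = 4) and 204.4 ± 7.87 CPM with enhancer guides (n = 4). It fell by 0.49 on the log2 scale with promoter guides (SE 0.0403, edgeR adjusted p = 6.08e-15), which is 28.6% lower. With enhancer guides it fell by 0.21 (SE 0.0400, adjusted p = 0.0204), which is 13.6% lower. In each group, 4 of 4 libraries lay below the lowest scramble library, and the exact permutation p was 0.00476, the smallest that 210 splits can give. CSF1 had the smallest p of all tested genes in both groups, and it was the 1 gene past the threshold in each. At an unadjusted p under 0.05 there were 519 genes with promoter guides and 520 with enhancer guides, and DESeq2 also called 1 gene in each. The promoter guides lowered CSF1 by more than the enhancer guides did, with a difference in log2 change of -0.27 (SE 0.0436, adjusted p = 0.000358). In the 30 super-enhancer groups the log2 change of CSF1 lay between -0.13 and 0.06, and none passed the threshold.

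Replicate 2 of each CSF1 group may differ from the others in guide set or replicate number. Without it CSF1 fell by 0.47 with promoter guides (adjusted p = 5.79e-12) and by 0.23 with enhancer guides (adjusted p = 0.0379, n = 3 each). The call for the enhancer guides depended on the libraries in the fit, though the log2 change stayed between -0.23 and -0.18. Leaving out a replicate number removed it from every target at once and kept it in the scrambles. A fit of that kind therefore does not show the weight of 1 library. The adjusted p was 0.964, 0.99996 and 0.993 without replicates 1, 3 and 4, and 0.0531, 0.0546, 0.102 and 0.135 without scramble 1 replicate 1, scramble 1 replicate 3, scramble 1 replicate 4 and scramble 2 replicate 1.

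**Figure D1:**
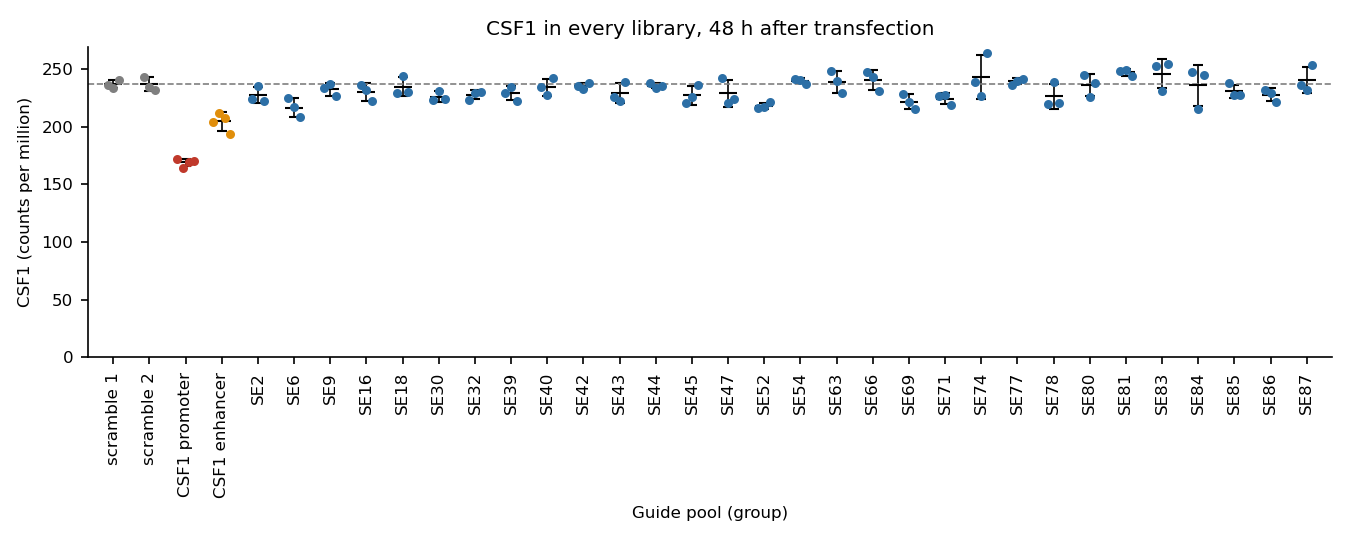
CSF1 in CPM in each library, by group, with the group mean and SD. The 4 libraries with promoter guides lie between 164.4 and 171.7 CPM and the 4 with enhancer guides between 193.6 and 212.1 CPM, all below the lowest scramble library at 231.7 CPM.

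As background, scramble 1 was compared with scramble 2. CSF1 was at 236.8 ± 3.56 CPM in scramble 1 and 236.5 ± 6.00 CPM in scramble 2 (SD, n = 3 each). EdgeR called 0 genes between them, with 3539 at an unadjusted p under 0.05, and DESeq2 called 4. The count was 2906 without scramble 2 replicate 3 and 1 without scramble 2 replicate 1. Libraries differed along transcript length. In 11 libraries the slope was above 0.2, so that long transcripts were higher and short ones lower. They were scramble 2 replicate 4 at 0.615, SE2 replicate 1 at 0.536, SE78 replicate 4 at 0.530, SE30 replicate 1 at 0.464, SE84 replicate 4 at 0.430, SE83 replicate 4 at 0.412, SE81 replicate 4 at 0.397, SE74 replicate 4 at 0.382, SE16 replicate 1 at 0.310, SE9 replicate 1 at 0.302 and SE2 replicate 3 at 0.296. The adjusted R2 of the slope on the group was 0.0121.

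**Figure D2:**
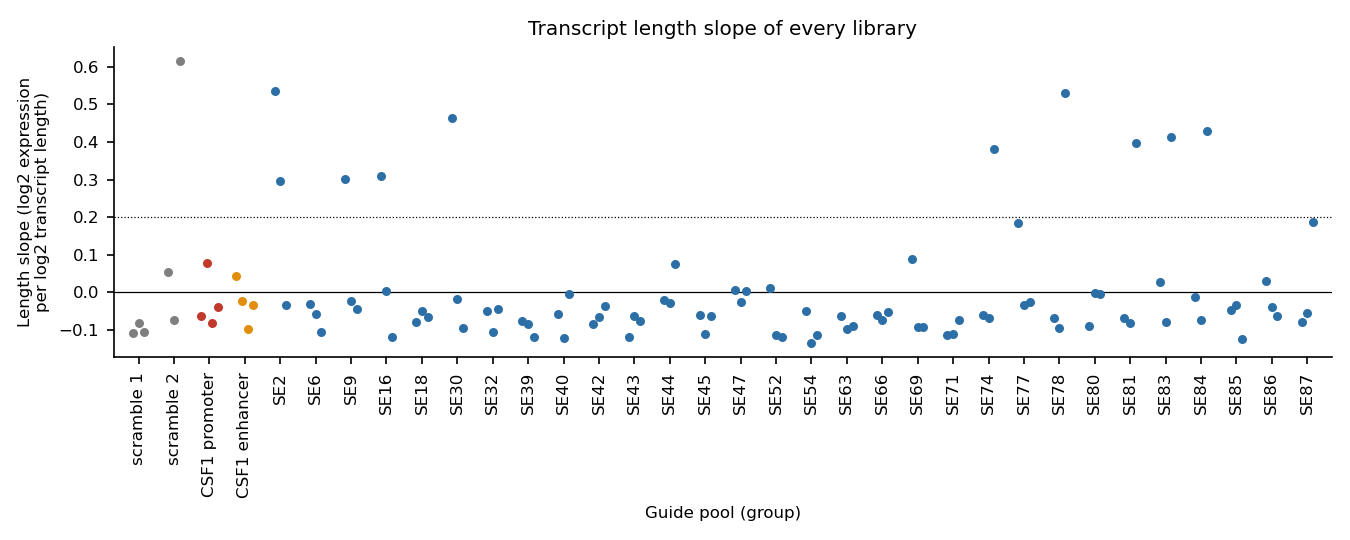
Slope of log2 expression on log2 transcript length in each library against all libraries, by group. Above 0.2 lie 11 libraries, the highest being scramble 2 replicate 4 at 0.615.

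The next question was which genes each super-enhancer moved against the scrambles. In the planned design 5 super-enhancers had a call. In SE52, GREM1, which encodes a secreted BMP antagonist, fell by 0.49 on the log2 scale (SE 0.0929, adjusted p = 0.0180), from 58.7 ± 5.94 CPM in the scrambles (n = 6) to 41.5 ± 4.65 CPM (n = 3). IFIT3, an interferon-induced antiviral gene, fell there by 0.60 (SE 0.120, adjusted p = 0.0355), from 66.5 ± 11.9 to 43.9 ± 2.98 CPM. In SE66, PODXL, the gene of the cell-surface sialomucin podocalyxin, fell by 0.48 (SE 0.0921, adjusted p = 0.0331), from 248.3 ± 20.1 to 178.4 ± 9.69 CPM. In SE84, EGR1, an immediate early transcription factor gene, rose by 0.53 (SE 0.0960, adjusted p = 0.00724), from 18.2 ± 1.64 to 26.3 ± 1.51 CPM. The rule for named genes required all 3 libraries of the target to lie on the side of the change. The direction of these changes was shared by most super-enhancers, all compared with the same scrambles. GREM1 was below 0 in 30 of 30, IFIT3 in 28, PODXL in 25 and EGR1 in 2.

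SE2 had 11 lower and 4 higher genes against the scrambles, and 2 of its 3 libraries had length slopes of 0.536 and 0.296. Lower genes included IRF7, a transcription factor of the interferon response, with a log2 change of -0.62 (SE 0.123, adjusted p = 0.0294) and 12 ± 2.29 against 18.5 ± 1.09 CPM. Among them were also the collagen genes COL7A1 (-0.56, 20.4 ± 2.30 against 30.1 ± 4.69 CPM) and COL16A1 (-0.65), the kinase genes MAP2K7 (-0.40) and CSNK1G2 (-0.34), the nuclear receptor gene NR2F6 (-0.50) and MEGF6 (-0.60). PLEKHF1 (-0.63), ZNF771 (-1.05), the pseudogene GOLGA2P10 (-0.62) and CTD-3092A11.1 (-1.11) completed the lower set. Higher genes were ELMO2, an engulfment and migration adaptor gene (0.29), ZNF2 (0.51), GPLD1 (1.17) and RP11-342K6.2 (2.51), the last chosen after its values were seen since 2 of 3 libraries lay on its side. Adjusted p for these genes ran from 0.0294 to 0.0393. Of these 15 genes, 0 passed without replicate 1, replicate 3, scramble 1 replicate 1 or scramble 1 replicate 4, 4 without scramble 2 replicate 3 and 9 without scramble 2 replicate 1. The direction of several of these changes was shared by most super-enhancers, all compared with the same scrambles. CTD-3092A11.1 and CSNK1G2 were below 0 in 30 of 30, ZNF771 and GOLGA2P10 in 29, NR2F6 in 28, COL7A1 in 27, MEGF6 in 26 and IRF7 in 24. GPLD1 was below 0 in 0 and RP11-342K6.2 in 3, while ELMO2 and ZNF2 were mixed, at 10 and 12.

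Over the 30 super-enhancers there were 22 calls against the scrambles, 14 lower and 8 higher, with a median of 0. In the 25 without a call, edgeR gave 360 to 1086 genes at an unadjusted p under 0.05, and DESeq2 called 0 to 4. With the replicate number as a block the summed count was 186 and the median 0.5, and with DESeq2 they were 73 and 1. The summed count was 12, 7 and 5182 without replicates 1, 3 and 4 of every target. It was 6 without scramble 1 replicate 1, 5 without scramble 1 replicate 4, 14 without scramble 2 replicate 3 and 2388 without scramble 2 replicate 4. Single genes moved too: GREM1 in SE52 had an adjusted p of 0.365 and 0.715 without replicates 1 and 4, and of 0.123 without scramble 1 replicate 3. IFIT3 had 0.0548, 0.99998 and 0.715 without replicates 1, 3 and 4, and 0.270, 0.106 and 0.669 without scramble 1 replicate 3, scramble 1 replicate 4 and scramble 2 replicate 4. PODXL in SE66 had 0.999996 and 0.940 without replicates 3 and 4, and 0.156, 0.0504 and 0.251 without scramble 1 replicate 1, scramble 1 replicate 3 and scramble 2 replicate 1. EGR1 in SE84 had 0.324 and 0.166 without replicates 1 and 3.

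The 3 calls of SE30 were haemoglobin genes, which mark red blood cells. HBB reached 322.4 CPM, HBA1 197.7 CPM and HBA2 145.3 CPM in SE30 replicate 3, against scramble means of 0.0518, 0.281 and 0.0346 CPM (n = 6). HBA1 rose with an adjusted p of 0.00145, and its log2 change was 0.69 with an adjusted p of 0.919 without replicate 3. HBB and HBA2 were chosen after their values were seen, because 1 of 3 libraries carried them. HBB also reached 96.8 CPM in SE87 replicate 1, 78.7 CPM in SE42 replicate 3, 66.1 CPM in SE63 replicate 1 and 6.66 CPM in SE32 replicate 3, and was above 1 CPM in 8 libraries of all groups. The list haematopoietic (other cell type), with 7 of its members tested, rose in these 5 super-enhancers, with adjusted p from 2.15e-10 in SE30 to 1.82e-05, and with 12 member calls adjusted over the list alone. With an estimated correlation all 5 held, at adjusted p from 0.000310 to 0.0295. CD68 and CD14, macrophage markers, had medians of 107 and 21.6 CPM and were above 1 CPM in every library. LYZ reached 1.93 CPM, in SE32 replicate 3, where the neutrophil gene LTF was also highest. LTF rose in SE32 against all other groups, with a log2 change of 4.62 (SE 0.583, adjusted p = 1.37e-07), and stood at 0.59 with an adjusted p of 1 without replicate 3.

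A length slope per library and the replicate number were then added to the fit, which is the adjusted design and was chosen after the data were seen. CSF1 fell by 0.48 with promoter guides (SE 0.0376, adjusted p = 1.10e-17) and by 0.21 with enhancer guides (SE 0.0375, adjusted p = 0.00253). Over the 30 super-enhancers there were 726 calls against the scrambles, 451 lower and 275 higher, with a median of 3.5 and a call in 22 super-enhancers. SE2 had 121 lower and 99 higher genes, SE6 79 and 65, SE71 45 and 23, SE52 47 and 11, and SE84 35 and 21.

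In SE52, RSAD2, the gene of the antiviral protein viperin, fell by 0.84 (SE 0.0709, adjusted p = 1.34e-15), from 67.9 ± 15.3 CPM in the scrambles (n = 6) to 36.5 ± 6.70 CPM (n = 3). IFIT2 (-0.60), DDX60 (-0.56), IFIT3 (-0.53) and OASL (-0.48) fell with it, as did IL7R, the interleukin 7 receptor gene (-0.54). PTX3, the gene of a secreted pattern recognition protein, rose by 0.40 and HAS3, a hyaluronan synthase gene, by 0.26. In SE6, KLF4, a Kruppel-like transcription factor gene, fell by 0.41 (adjusted p = 3.76e-07) and ZC3HAV1, an antiviral zinc finger gene, by 0.23. In SE71, S100A4, a calcium-binding protein gene, fell by 0.90 (adjusted p = 1.92e-07). ODC1, the rate-limiting enzyme of polyamine synthesis, rose by 0.33 and IL1B, the interleukin 1 beta gene, by 0.38 in SE71. In SE84, SLIT2 (-0.46), ARG2, the mitochondrial arginase gene (-0.43), the Wnt inhibitor gene DKK1 (-0.41), the plakoglobin gene JUP (-0.39) and AKR1B1, an aldose reductase gene (-0.32), fell, while EGR1 (0.54), ARRDC4 (0.31) and the clock gene NR1D1 (0.26) rose. In SE2, COL5A1 fell by 0.36, and SPAG5, a mitotic spindle gene, rose by 0.23.

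Many of these genes moved the same way in several super-enhancers. In the adjusted design, RSAD2 fell in 14 of 30 super-enhancers, and IL7R and IFIT2 in 11 each, with mean log2 changes over all 30 of -0.33, -0.24 and -0.24. RSAD2 was at 53.3 ± 11.1 CPM in the 90 super-enhancer libraries and at 67.9 ± 15.3 CPM in the 6 scramble libraries. The chemokine gene CCL5, ISG15, KLF4 and GPRC5A fell in 8 each, and DDX60 and GREM1 in 7. IL1B rose in 12 (mean 0.16), ODC1 in 11 (0.17), SERPINB2, a plasminogen activator inhibitor gene, in 9 (0.21), and the thrombomodulin gene THBD in 8 (0.23). ALOXE3, HMGA2 and GADD45A rose in 4 each, and EGR1, CXCL8 and GNPDA1 in 3. The libraries with CSF1 guides moved the same way for RSAD2 (-0.38 with promoter guides, adjusted p = 0.000291, and -0.39 with enhancer guides, adjusted p = 0.000998). So did IL7R (-0.32 and -0.27), ODC1 (0.25 and 0.19) and IL1B (0.25 and 0.24), each with an adjusted p of 0.0300 or lower. In the planned design, edgeR and DESeq2 found 0 genes changed the same way in at least 10 super-enhancers, and 170 were at an unadjusted p under 0.05 in at least 10. All these comparisons share the 6 scramble libraries, and no count without an effect was made at the unadjusted threshold, so the 170 cannot be read as a response.

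With CSF1 promoter guides in the adjusted design, NID2, a basement membrane gene (-0.33), SLIT2 (-0.28) and C10orf10 (-0.59) were lower than in the scrambles, and KLF10 (0.36), UPP1 (0.22) and THBD (0.32) higher. With enhancer guides DDX60 was lower (-0.31) and ZNF317 (0.22) and MAPKAP1 (0.19) higher. DDX60 was also lower in 7 super-enhancers and THBD higher in 8. SLIT2 was also lower in SE84, and KLF10 was higher there (0.36, adjusted p = 0.00402). The changes of these genes are thus not particular to the CSF1 guides, and those of the other genes named here may not be either. The sets of the promoter and the enhancer guides held 15 and 9 genes, against 1 and 1 in the planned design.

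**Figure D3:**
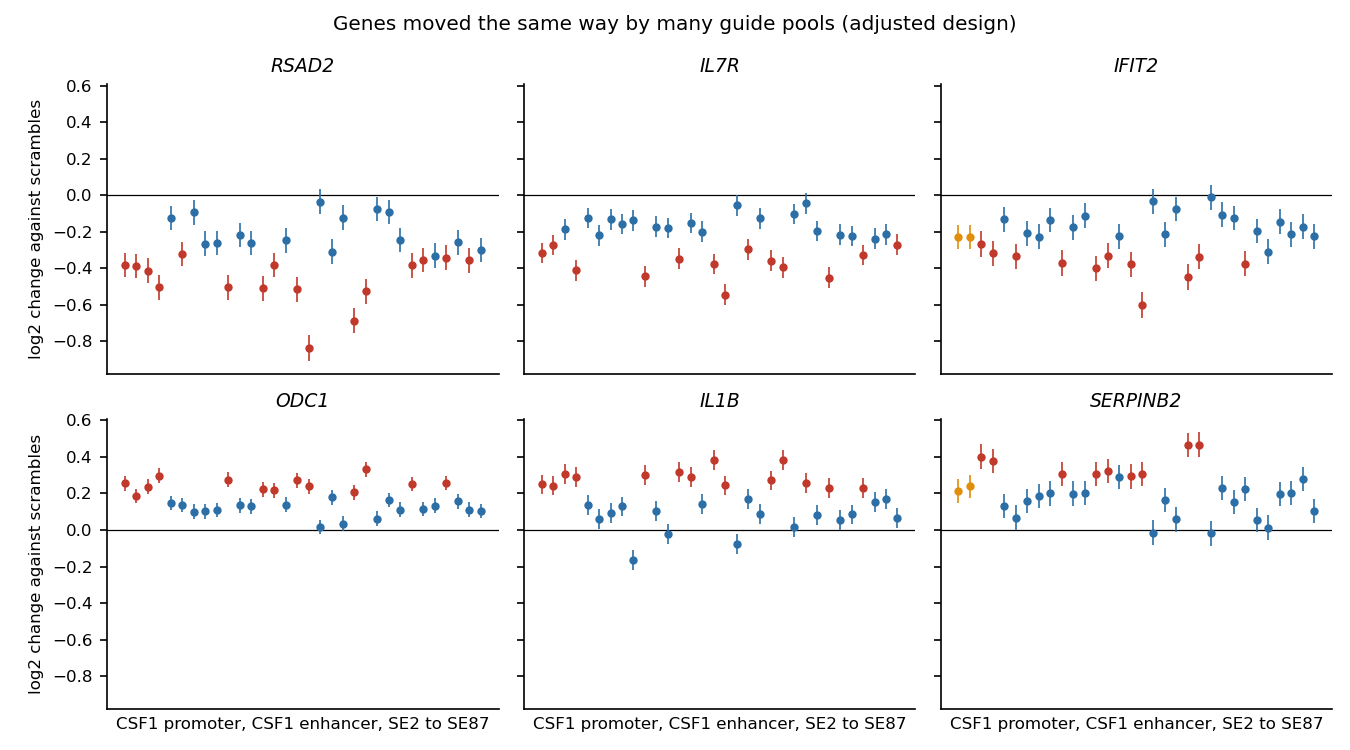
Log2 change against the scrambles in the adjusted design for genes that moved in many super-enhancers, with a point per target. RSAD2 lies below 0 in 30 of 30 super-enhancers and ODC1 below 0 in 0 of 30.

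Camera made 93 list calls in the planned design over the 30 super-enhancers, and 7 held with an estimated correlation. The interferon response list, with 24 tested members, fell in 20 super-enhancers and rose in 0, and its median log2 change was -0.40 in SE52 and -0.25 in SE69. With an estimated correlation it held in SE52 (adjusted p = 0.00788) and SE69 (adjusted p = 0.0295). Member calls adjusted over the list alone were 17 lower and 0 higher, against 2 over all genes, IRF7 in SE2 and IFIT3 in SE52. Cytosolic ribosomal protein genes, whose transcripts are short, rose in 16 super-enhancers and fell in 4, which were SE2, SE30, SE83 and SE84. The ATF4 stress response rose in 13, immediate early genes in 7, NF-kB and cytokines in 5, and mitochondrial genome transcripts rose in 3 and fell in 2, while the ER unfolded protein response fell in 1. For these and the ribosomal list the smallest adjusted p was 0.890 with an estimated correlation. DNA replication and mitosis rose in 3 each and p53 targets in 2 (adjusted p = 0.878 with an estimated correlation for all 3 lists), and YAP and TEAD targets fell in 4 and cholesterol synthesis in 1 (adjusted p = 0.504 with an estimated correlation). Histones rose in 2 (adjusted p = 0.747 with an estimated correlation), the basal list fell in 1 (0.181 with it), and the mesenchymal list rose in 1 (0.112 with it). The luminal, epithelial, fibroblast, hypoxia, matrix protease and TGF-beta lists had 0 calls, with smallest adjusted p from 0.0502 for fibroblast to 0.209 for luminal. The number of list calls was 52 without scramble 2 replicate 4.

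In the adjusted design there were 113 list calls. The interferon response list fell in 26 super-enhancers, in 22 with an estimated correlation, and had 185 lower and 0 higher member calls adjusted over the list alone, against 68 over all genes. It also fell with the CSF1 promoter guides (adjusted p = 1.60e-13) and enhancer guides (adjusted p = 2.09e-13). In 1 call of this list the mean of its members had the other sign than the test. The ATF4 list rose in 16, with 2 held at the estimated correlation, and 47 member calls higher and 3 lower adjusted over the list alone. They included ATF3 in SE84 (0.29, adjusted p = 0.00106), STC2 in SE6 (0.22) and the amino acid transporter gene SLC3A2 in SE84 (0.18). NF-kB and cytokines rose in 8, with 4 held, led by IL1B in SE47 (0.38) and CXCL8 in SE6 (0.26). Cholesterol synthesis fell in 8 with 2 held (INSIG1 in SE52, -0.17), DNA replication rose in 3 with 2 held, the haematopoietic list rose in 6 with 4 held, and the matrix protease list rose in 1, which held.

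Other lists lost their calls with the estimated correlation. Mitosis rose in 14 (adjusted p = 0.132 with an estimated correlation, CENPF in SE6 at 0.13), hypoxia and glycolysis fell in 6 and rose in 1 (0.0624 with it, MXI1 in SE6 at -0.28), and ribosomal genes fell in 5 (0.278 with it). Mitochondrial transcripts fell in 2 and rose in 4 (0.571 with it), TGF-beta targets fell in 3 (0.0834 with it), and the ER unfolded protein response fell in 3 (0.123 with it). The fibroblast list fell in 1 (0.0826 with it), the epithelial list in 1 (0.0598 with it), the basal list in 1 (0.223 with it, SOX9 in SE6 at -0.31), and YAP and TEAD targets in 1 (0.210 with it). The mesenchymal list rose in 1 (0.0874 with it, with TWIST1 in SE6 at -0.47 and NT5E in SE71 at 0.21), immediate early genes in 1 (0.468 with it) and histones in 1 (0.226 with it). P53 targets and the luminal list had 0 calls, with smallest adjusted p of 0.0562 and 0.223.

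To ask which genes moved under 1 target, each super-enhancer was compared with all other groups. In the adjusted design, PODXL (chromosome 7, start 131500262) fell in SE66 by 0.35 (SE 0.0367, adjusted p = 5.06e-11), from 231.2 ± 22.1 CPM in the other 101 libraries to 178.4 ± 9.69 CPM (n = 3). CTSB, the lysosomal protease cathepsin B (chromosome 8, start 11842524), fell in SE45 by 0.24 (SE 0.0257, adjusted p = 1.65e-10), from 1391 ± 119 to 1229 ± 22.9 CPM. ALDH1A3, a retinaldehyde dehydrogenase gene (chromosome 15, start 100877714), fell in SE87 by 0.33 (SE 0.0420, adjusted p = 1.21e-07), from 1480 ± 187 to 1159 ± 215 CPM. FGF2, the basic fibroblast growth factor gene (chromosome 4, start 122826708), fell in SE74 by 0.28 (SE 0.0362, adjusted p = 1.87e-07), from 532.3 ± 61.9 to 462.4 ± 68.8 CPM. The cytokine genes IL1B (chromosome 2, start 112829751) and IL1A (start 112773915) fell in SE32 by 0.33 (adjusted p = 4.37e-06) and in SE42 by 0.40 (adjusted p = 0.000954). Against the scrambles, SE32 and SE42 had 0 calls in the adjusted design, with IL1A in SE42 at -0.31 (adjusted p = 0.702). IL1B was called higher than in the scrambles in 12 super-enhancers. Its fall in SE32 is thus partly against groups in which it was raised. Against all other groups, ARG2 (chromosome 14, start 67619798) fell in SE84 by 0.43 (adjusted p = 6.04e-05). These 7 genes passed in all 3 further designs, but in the planned design only ARG2 of them passed. Each was picked as the lower gene with the smallest p in its super-enhancer, a choice that favours the lowest of all targets. Of the 30 genes picked in this way 18 passed in the adjusted design, and 15 of these 18 were the lowest of all 32 targets. FGF2 and ARG2 in SE84 were chosen after their values were seen, since FGF2 was below the mean in 2 of 3 libraries and ARG2 fell outside the rule for SE84.

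Further genes passed in the adjusted design and not in every other one. AFAP1, an actin filament gene (chromosome 4, start 7758714), fell in SE16 by 0.24 (adjusted p = 6.97e-07), and its adjusted p was 0.464 with the length slope alone. Without SE16 replicate 4 its log2 change was -0.15 (limma-trend adjusted p = 0.0385). RSAD2 fell in SE52 (-0.54) and SE69 (-0.39), BHLHE40, a basic helix-loop-helix repressor gene, in SE69 (-0.19), AKR1B1 in SE71 (-0.29), SE39 (-0.24) and SE47 (-0.22), S100A4 in SE39 (-0.61), ZC3HAV1 in SE6 (-0.15), ADI1 in SE77 (-0.23), IL1B in SE54 (-0.24), MYH15 in SE47 (-0.54), and the pseudogene HTR7P1 in SE9 (-1.11). MAP3K10, a kinase gene, fell in SE2 by 0.48 (adjusted p = 0.0107). The deoxyribonuclease gene DNASE1 rose in SE87 (0.28), UPP1 in SE39 (0.18), IL1B in SE47 (0.23), CCL5 in SE54 (0.26) and SERPINB2 in SE69 (0.27). AKR1B1 in SE71, IL1B in SE54, ZC3HAV1, MAP3K10 and RSAD2 in SE52 were chosen after their values were seen, each as the lower gene with the smallest p in its super-enhancer.

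Without the adjustment, in the planned design, adjusted p was 0.147 for PODXL, 0.991 for CTSB, 1 for ALDH1A3, 0.940 for FGF2, 1 for IL1B in SE32, 1 for IL1A in SE42, 0.964 for AFAP1, 0.00313 for ARG2 and 0.00592 for MAP3K10, and of these only ARG2 and MAP3K10 passed. In that design ARG2 had an adjusted p of 1 without replicate 4, and MAP3K10 had 0.546 and 0.148 without replicates 1 and 3. Each of these replicate numbers was left out of every target at once. Without the libraries of a length slope above 0.2, neither gene passed. Single libraries decided some calls in the adjusted design. IL1A in SE42 had an adjusted p of 0.0746 without SE42 replicate 1, ARG2 0.244 without SE84 replicate 4, ZC3HAV1 0.0692 without SE6 replicate 3, S100A4 0.112 without SE39 replicate 1, and HTR7P1 0.171 without SE9 replicate 3. ADI1 had 0.101, 0.271 and 0.122 without SE77 replicates 1, 3 and 4, IL1B in SE54 had 0.927 and 0.458 without SE54 replicates 3 and 4, and AKR1B1 in SE47 had 0.391 and 0.622 without SE47 replicates 1 and 3. PODXL, CTSB, ALDH1A3, FGF2 and IL1B in SE32 passed with any of their 3 libraries left out, with a highest adjusted p of 4.22e-07, 1.79e-06, 0.00937, 0.00155 and 0.0162.

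**Figure D4:**
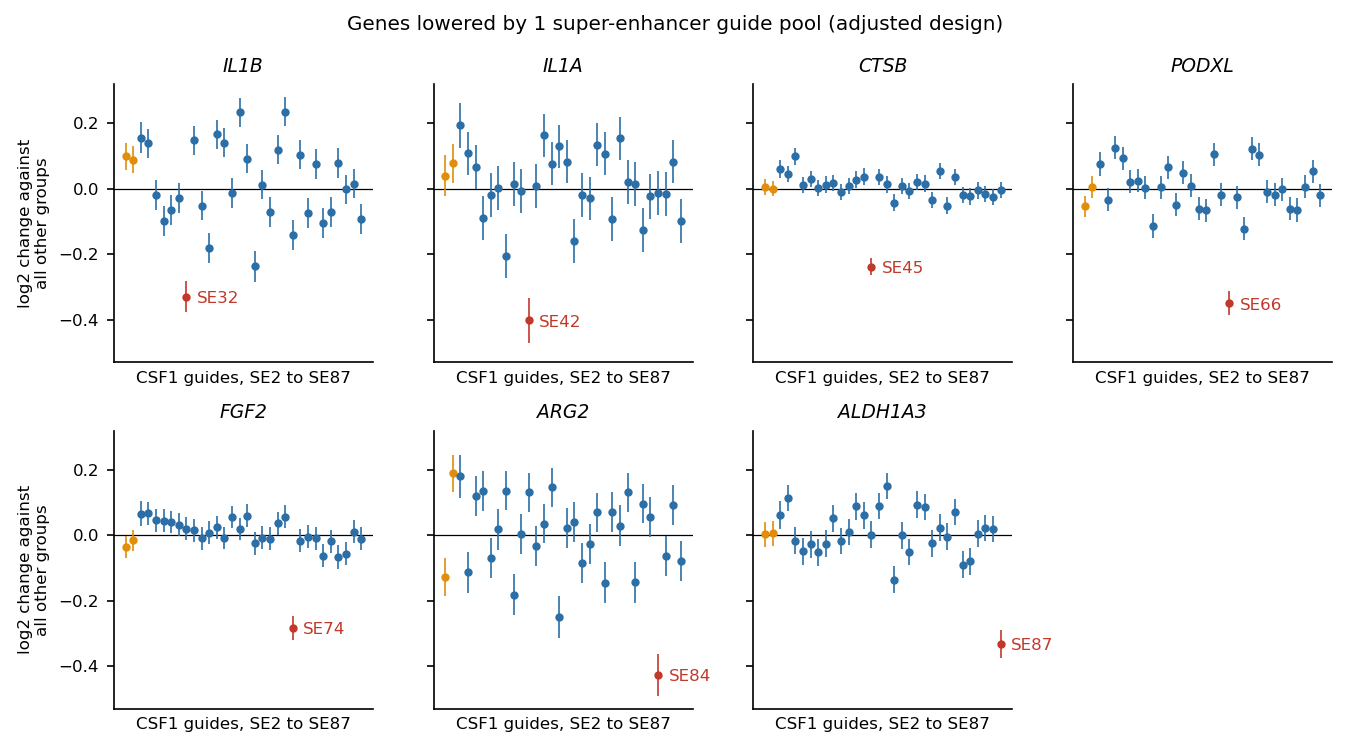
Log2 change of each named gene against all other groups in the adjusted design, with a point per target and the super-enhancer in which the gene fell marked. PODXL in SE66 at -0.35 and CTSB in SE45 at -0.24 are marked.

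SE2 stood apart in the planned comparison with all other groups. It had 943 lower and 2041 higher genes, of 3056 calls summed over the 30 super-enhancers. The lower genes had a median transcript length of 2305 nt and the higher genes of 6522 nt, against 3517 nt for all tested genes, and SE2 replicates 1 and 3 had length slopes of 0.536 and 0.296. With the length slope alone in the fit, the summed count was 67, and in the adjusted design it was 255, with 139 lower and 116 higher genes and a call in 24 super-enhancers. The summed count was 96, 38 and 8990 without replicates 1, 3 and 4 of every target. Other calls in the planned comparison were LRRD1 in SE9, with a log2 change of 4.20 (adjusted p = 0.000168) that had an adjusted p of 1 without replicate 1, and RNaseP_nuc in SE81, with 2.75 (adjusted p = 1.41e-05, and 0.0976 in the adjusted design).

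Neighbouring genes that were lower together were looked for around every tested gene. No window of the planned design lay below all 100 random sets. In the adjusted design 1 did. It was SE2, around OPLAH on chromosome 8 from 143553207 to 144605816, where 46 of 52 genes were below 0 and the scaled sum was -12.5, against a lowest random sum of -10.0. With 30 super-enhancers set against 100 random sets each, chance can also give 1 such window. SE2 replicates 1 and 3 had length slopes of 0.536 and 0.296, and 0 of the 119 genes called in SE2 against all other groups by edgeR in the adjusted design passed with a GC slope added. The median change of those 119 genes went from 0.31 (median SE 0.0755) to 0.21 (median SE 0.0634). The window itself was not computed with a GC slope. In the planned design the sum of that window was -11.8, and 1 of 100 random sets was as low. Its members include PLEC, the plectin gene, EEF1D, a translation factor gene, and HSF1, the heat shock transcription factor gene.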

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

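The tests of transcript length and GC content as the source of the SE2 calls were chosen after those calls were seen, and every count in the adjusted design uses a design chosen after the data were seen.

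Of 18 groups and measures tested for a sample far from the others, 2 stood out, and chance alone marks about 1 in 20. The GC slope of CSF1 promoter replicate 2 was -0.707, and the next of the 4 libraries was at 0.183. The length slope of scramble 2 replicate 4 was 0.615, and the next of the 6 scramble libraries was at 0.0553. The CSF1 log2 change differed between the promoter and the enhancer guides by -0.27 (SE 0.0436, edgeR adjusted p = 0.000358).

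The many calls of SE2 against all other groups were weighed first. With the length slope of each library in the fit, the number of calls of SE2 was 0.268% of the 2984 before, and 5 of those genes were still called. The median change of those genes, along their direction, went from 0.41 (median SE 0.127) to 0.08 (median SE 0.0651), so the calls ended because the changes shrank. The slope was computed from the same expression values. It had an absolute correlation of 0.996 with the first principal component, the main axis of variation between libraries. Any difference along that axis would shrink in this fit, whatever its cause. The loss of calls thus cannot tell a gradient of transcript length from another cause along that axis. Of the calls left in the adjusted design, 0% were left with the GC slope added, and the median change of those 119 genes went from 0.31 (median SE 0.0755) to 0.21 (median SE 0.0634), so a GC gradient may account for part of these. An effect of the SE2 guides on single genes stays open, MAP3K10 among them, with an adjusted p of 0.0107 in the adjusted design and 0.0915 with the GC slope.

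The second pattern is that interferon-response genes and IL7R were lower and ODC1 and IL1B higher than in the scrambles in many super-enhancers. Chance values of the 6 shared scramble libraries are argued against but not excluded. In the adjusted design, 1 of 100 reassignments of the labels, the real one, gave as many shared genes (real 7, highest other 0). The reassignments did not keep the replicate numbers balanced as they are in the real groups. For the interferon list, a single aberrant scramble library is argued against too. Its median over the super-enhancers in the planned design stayed between -0.18 and -0.11 (closest to 0 at -0.107) with any of the 6 left out. For the same list, a fault of 1 scramble pool is argued against by values of -0.17 against scramble 1 and -0.124 against scramble 2 alone. IL7R, ODC1 and IL1B were not tested for these 2 explanations. A response to any guide pool with a genomic target, CSF1 guides included, may explain the pattern, and a difference in plate position or culture between scrambles and targets was not tested, so the pattern is not shown to come from the super-enhancers.

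Other assignments of the libraries to groups were counted for each result with limma-trend, whose own counts are given here. In the planned design, 17 of 100 splits gave as many genes as the CSF1 promoter guides (real 1, highest other 3), so chance is not excluded for that count. For the enhancer guides 2 of 100 did (real 1, highest other 1), a share under 0.05. A count of 1 gene that another split also reached is too coarse to exclude chance. For scramble 1 against scramble 2 all 10 of 10 splits were as high (real 0, highest other 0), and 10 splits are too few for a share under 0.05. Chance is not excluded for the calls against the scrambles summed over 30 super-enhancers (49 of 100, real 47, highest other 15799), the calls against all other groups (56 of 100, real 2973, highest other 18543) or the list calls (22 of 100, real 87, highest other 118). The median per super-enhancer and the genes shared by at least 10 were 0, so all 100 of 100 splits were as high (highest other 0 for both) and these counts decide nothing. Splits with many times the real count point to a structure of the samples, and which libraries made them high was not tested.

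The number of super-enhancers with a lower gene against all other groups was reached by 77 of 100 splits in the planned design (real 7, highest other 13), so chance is not excluded. In the adjusted design it was reached by 1 of 100 (real 21, highest other 14). Those splits did not keep the replicate numbers balanced as they are in the real groups, so this share does not exclude chance.

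For single super-enhancers against the scrambles in the planned design, chance is not excluded for SE84 (17 of 84, real 2, highest other 8179), SE52 (14 of 84, real 2, highest other 3577), SE30 (20 of 84, real 1, highest other 8591), SE66 (19 of 84, real 1, highest other 31) or SE2 (14 of 84, real 41, highest other 9501). Against all other groups it is not excluded for SE84 (12 of 100, real 2) or SE30 (29 of 100, real 1), each with a highest other of 7678. For SE32 limma-trend gave 0 genes, so all 100 of 100 splits were as high, which says nothing on the calls of edgeR there. For SE2 2 of 100 were as high (real 3436, highest other 7678), but SE2 was picked for its count among 30 super-enhancers, so chance is not excluded there either. The high splits point to the same structure. Against all other groups the highest other count was 8351 with the replicate block alone, and 123 with the length slope also in the fit. The high counts there thus went with the length slope, which was computed from the same libraries.

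In the adjusted design, the share of splits as high was under 0.05 for the CSF1 promoter guides (2 of 100, real 19, highest other 21) and the enhancer guides (3 of 100, real 10, highest other 119). It was also under 0.05 for the calls summed against the scrambles (4 of 100, real 1061, highest other 1695) and their median (1 of 100, real 4.5, highest other 0). The same held for the shared genes (1 of 100, real 7, highest other 0) and the list calls (1 of 100, highest other 85). These splits did not keep the replicate numbers balanced as they are in the real groups, and the design was chosen after the data were seen. These shares therefore do not exclude chance. Nor is chance excluded for the calls summed against all other groups (20 of 100, real 498, highest other 1658), where the high splits again point to structure. Scramble 1 against scramble 2 gave 10 of 10 (real 0, highest other 0), and 10 splits are too few. The single super-enhancers were picked among 30 for their counts, so a share under 0.05 does not exclude chance for any 1 of them. Against the scrambles the shares were 3 of 84 for SE6 (real 129, highest other 146), 1 of 84 for SE71 (real 71, highest other 63), 1 of 84 for SE52 (real 58, highest other 32), 4 of 84 for SE84 (real 77, highest other 309) and 5 of 84 for SE2 (real 505, highest other 1018). Against all other groups, with a highest other of 123, they were 1 of 100 for SE2 (real 318), 4 of 100 for SE84 (real 36), 5 of 100 for SE52 (real 30), 13 of 100 for SE39 (real 10) and 43 of 100 for SE30 (real 1).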

How the results depend on the processing

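Tests with a length or GC slope, without the steep libraries, and with single target libraries left out by limma-trend were chosen after the data were seen. Of 238 values of the summary results under other settings, 157 kept their direction and side of the threshold or stayed within 1.5 times, 12 kept their direction and lost the threshold, 69 counts moved by more than 1.5 times and 0 reversed. RLE size factors in place of TMM and a filter at 5 CPM moved none of the summary results. CSF1 fell with promoter guides by a log2 change between -0.49 and -0.47 over 22 other settings and passed in 21. With enhancer guides it lay between -0.23 and -0.18 and passed in 11, with a largest unadjusted p of 0.0111. Unless a reason is given, the cause was not tested.

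With an estimated inter-gene correlation the list calls were 7 in place of 93. With no filter on low counts, which tests more genes, CSF1 with enhancer guides was at -0.21 (adjusted p = 1), the count with enhancer guides was 0, the sum against the scrambles 2 and the sum against all other groups 9786. With the DESeq2 Wald test, scramble 1 against scramble 2 gave 4 genes, the sum against the scrambles was 73 and the median 1. With the replicate block alone, the promoter guides gave 4 genes, the enhancer guides 2, the sum against the scrambles was 186, the median 0.5 and the shared genes 1. With fewer control libraries, scramble 1 alone gave -0.21 for CSF1 with enhancer guides (adjusted p = 0.385), 0 genes there and a sum of 5, and scramble 2 alone gave -0.21 (adjusted p = 0.217), 0 genes and a sum of 4. With only the target and the scrambles in the fit, and so fewer samples, CSF1 was at -0.48 with promoter guides (adjusted p = 0.280) and at -0.21 with enhancer guides (adjusted p = 1), with 0 and 0 genes and a sum of 0. At an adjusted p of 0.01, the enhancer guides had 0 genes, and the sums were 3 and 71. With at least 1.5-fold the promoter and enhancer guides had 0 and 0 genes, and the sums were 13 and 755. With the adjustment over all 32 targets together, the enhancer guides had 0 genes, and the sums were 2 and 60.

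With the length slope, the promoter guides had 2 genes, the sum against the scrambles was 59 and that against all other groups 67. With the replicate block and length slope, the promoter and enhancer guides had 15 and 9 genes, the sum against the scrambles was 726, the median 3.5, the shared genes 6, the sum against all other groups 255 and the super-enhancers with a window of lower genes 1. With the GC slope added to these, the values were 31 and 16 genes, 2 between the scrambles, 1246, 8, 14 and 279. Without the 11 libraries of a length slope above 0.2, the promoter guides had 2 genes, and the sum against all other groups was 57. The planned design did not use the replicate number, which holds some shared variation: mean correlations of libraries with the same number, 1 to 4, were 0.0653, 0.00208, 0.0569 and 0.0199, against -0.0340, -0.00448, -0.0193 and -0.0118 with other numbers, and 59 libraries were closest to their own number.

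With each target replicate number and each scramble library left out in turn, with the spread pooled over groups, CSF1 lay between -0.49 and -0.47 with promoter guides and between -0.23 and -0.18 with enhancer guides. The number of genes ranged from 1 to 2 with promoter guides, from 0 to 1 with enhancer guides and from 0 to 2906 between the scrambles (2906 without scramble 2 replicate 3, 1 without scramble 2 replicate 1). The sum against the scrambles ranged from 5 to 5182 (5182 without replicate 4, 2388 without scramble 2 replicate 4), that against all other groups from 38 to 8990 (96, 38 and 8990 without replicates 1, 3 and 4) and the list calls from 52 to 132 (52 without scramble 2 replicate 4). The median and the shared genes stayed at 0.

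For single named genes past the threshold, 381 of 628 values kept their side, 244 lost it and 3 reversed. Of 2864 values of genes not past it, 368 gained it. The reversed values were HBB (-3.19, adjusted p = 0.917) and HBA2 (-1.82, adjusted p = 0.99996) in SE30 without replicate 3, the 1 library that carried them, and RP11-342K6.2 in SE2 (-0.17, adjusted p = 1) without the steep libraries. These genes were near 0 in most libraries, so their fitted values depend on the prior count. Genes followed with single target libraries left out, replicate block and length slope in the fit and limma-trend, passed in 37 of 54 values where they had not passed in the planned design, and ARG2 and MAP3K10, which had, kept 5 of 6 in this fit (ARG2 had an adjusted p of 0.244 without SE84 replicate 4). At 16223730 to 28063763 counts per library and 3 libraries per super-enhancer, edgeR recovered 38% of 50 simulated log2 changes of 0.5, and other depths were not simulated. The simulated counts held no gradient of transcript length and no effect of the replicate number. Recovery in the real libraries may therefore differ.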

Other observations

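Several super-enhancers without a call in the planned design had calls against the scrambles in the adjusted design, which was chosen after the data were seen. SE39 had 31 lower and 12 higher genes, SE47 21 and 12, SE80 19 and 10, SE69 17 and 5, and SE43 10 and 4. In SE39, S100A4 stood at a log2 change of -0.94 (SE 0.120, edgeR adjusted p = 9.67e-08). Against all other groups, the lower gene with the smallest p did not pass in several super-enhancers of the adjusted design: TRIB1, a pseudokinase gene, in SE18 (-0.23, adjusted p = 0.136), RAI14 in SE44 (-0.12, adjusted p = 0.0635), RAB18 in SE81 (-0.23, adjusted p = 0.0802) and THBD in SE86 (-0.29, adjusted p = 0.0892). These 4 were chosen after their values were seen.

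The pair of cytokine genes IL1A and IL1B lie next to each other on chromosome 2, and each fell in a different super-enhancer, which raised the hypothesis that guides lower the neighbourhood of the most lowered gene of a super-enhancer. IL1A was at -0.21 in SE32 (adjusted p = 1), where IL1B fell, and IL1B at -0.18 in SE42 (adjusted p = 0.267), where IL1A fell. The 2 genes also moved together in other groups, with IL1B at -0.24 and IL1A at -0.16 in SE54, and 0.23 and 0.13 in SE47. In others their signs differed, as in SE9 (-0.02 and 0.07). Joint movement is thus not particular to SE32 and SE42. Over the 30 super-enhancers, the mean z of the neighbours of the most lowered gene was -0.196 in the adjusted design, and 5 of 100 reassignments of the libraries, the real one included, were as low (lowest other -0.285). In the planned design the mean was -0.108, and 15 of 100 were as low (lowest other -0.312), so chance is not excluded there. The share in the adjusted design lies on the 5% limit, so whether the neighbourhood may be lowered with its gene cannot be told from these data. At least 2 lower neighbours at an unadjusted p under 0.05 were found in 3 super-enhancers.

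Libraries were checked for duplicates. Over 108 pairs of libraries of the same group and 14973 genes, the chi-square per gene ran from 3.14 to 204, with a median of 10.9, and 0 pairs were identical.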
